A study of Mus musculus with 6 samples.

How the data were processed

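Single-cell RNA libraries (10x Genomics, 3′ version 2 chemistry per the labels) had been made from heart cells sorted as endothelial, 3 libraries from Cre-negative (WT) and 3 from Cre-positive Nogo-deleted (KO) ApoE-deficient mice. Cell Ranger, with no version given, Seurat 4 and the mm10 genome are named in the submitters' processing notes, which give neither their roles nor their settings. The sort markers, the Cre line and the deleted exons are not given in the sources used here. Each deposited table holds 20125 genes by cells, and its deposited values are natural log values, ln(1 + x), where x was a whole number in 100% of the nonzero entries (within 1e-06). These whole numbers are called counts here. Their totals per cell span only 2653 to 7899, far narrower than raw molecule counts of droplet cells, so they look like counts corrected for depth before deposit, which is an inference from the values and is not recorded in the labels. A count test needs raw counts, so none was used, and limma on mean log values per library took its place. This had been fixed before the data were examined for the test over all endothelial cells, and was extended here to the tests within classes, between classes and of gene lists.

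Cells with at least 500 genes and at most 10% mitochondrial counts were kept, which removed 19 of 43405. Scrublet's own threshold marked 0.014% to 1.43% of a library, under 0.5% in 4 of the libraries, so the planned use of its calls was given up and the cells with the highest Scrublet scores were removed instead, at 0.8% of a library per 1000 cells (2537 cells). Clusters came from scanpy 1.11.5 with Leiden at resolution 1 on 2000 variable genes, leaving out Rtn4 and sex-linked, mitochondrial and ribosomal genes, 30 principal components and 15 neighbours, and proliferating clusters were split again at resolution 0.5. A cluster was called X-like where at least 3 fixed markers were raised and that type led its rivals among the top 10 genes by fold, and otherwise kept its number. All 22 marker lists served this naming, and those of other cell types were also summed over endothelial cells. Clusters 33 to 41 came nearly entirely from KO1 and were not counted as endothelial, although clusters 39, 40 and 41 had pan-endothelial scores above 0 (0.559, 0.147 and 0.602). Of these, cluster 36, with 30 of its 31 cells from KO1, counts among the macrophage and monocyte-like cells, as does cluster 20, with 83 of its 113 cells from KO1. Genes detected per cell and shares of cells with a count depend on depth, so Rtn4 shares are also given with every cell thinned to 2500 counts.

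Expression was tested with limma 3.58.1 in R 4.3.3 (moderated test with a trend, two-sided, Benjamini-Hochberg) on the mean deposited log value per library in log2 units, KO against WT with 3 libraries each, over all endothelial cells and in each endothelial class with at least 20 cells in every library. Genes needed at least 10 counts at the median library size in 3 libraries and 15 counts in all. The difference between classes was tested, KO against WT, on the value in capillary-like cells less that in artery-like or vein-like cells, taken within each library. Gene lists were tested with camera at a correlation of 0.01, and with an estimated correlation and fry. Camera compares a list with all other genes, and fry tests the list by itself. A direction given by camera is therefore relative to the other genes. Shares and single values were compared with exact two-sided permutation tests, for which 0.1 is the smallest p. Levels are printed as CPM of counts summed over a library's cells, scaled by trimmed mean of M values, with the SD over 3 libraries. The precision rests on 97721223 endothelial counts in 6 libraries of 13475253 to 21773615. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9 were used. Coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 names.

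Named genes followed a rule fixed in advance. It took 18 genes whatever their values, then up to 12 per direction past the threshold over all endothelial cells with at least 10 CPM and complete separation of the groups, without clone-like names, filled to 6 per direction by smallest p where fewer passed. It also took up to 4 members per list by smallest p, up to 4 per direction and class under the same conditions, 4 per class difference, and leading genes of clusters. Of the list members taken, some are left out where a list is described briefly, a choice made with their values in view, and 1 more is not reported here. Ltc4s over all endothelial cells was named after its values were seen. The gene lists number 28, of which 27 were tested. The replicate numbers gave no clear pairing of the libraries, and the values in the closing section cannot exclude one. A check for libraries deposited more than once found none, the chi-square per degree of freedom being 12.8 to 36.7 over all pairs. As the values are not raw counts, this number is no measure of sampling noise.

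The methods were tested on simulated data, with 1000 cells per library over all endothelial cells and an assumed coefficient of variation of 0.15 between libraries. The real libraries hold more cells and fall into sets described in the results, and these sets were not simulated. The shares recovered are therefore not those of the real libraries and may be higher or lower. With 11117 genes simulated for the comparison over all endothelial cells, limma on mean log values recovered 100% of 4-fold rises and 96.6% of 4-fold falls. It recovered 82.9% and 45.7% of 2-fold changes and 20% and 8.8% of 1.5-fold changes, calling 8 unchanged genes. In a run with no gene changed it called 0 of 11116 genes. For the class difference (10563 genes) it recovered 96.7% of 4-fold rises and 42.9% of 4-fold falls, and 20% and 28.1% of 2-fold changes, calling 6 unchanged genes, more than the 4 genes called in the real data. The second class of that simulation held fewer cells and no changed gene. With 20 random lists 0 were called. The simulated library effects were drawn separately for each gene, so this run cannot show how camera treats lists of correlated genes. For the same reason the run with no gene changed cannot show how many genes are called when libraries fall into sets.

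Several choices were made after values had been seen. The scale of printed levels was changed from mean count per cell to scaled CPM, because the median log2 ratio of all genes was 0.197 on the first scale and 0.012 on the other. This took the Rtn4 log2 ratio from -0.82 to -1.00, its KO level in T and NK cell-like and neutrophil-like cells from 89.3% and 90.2% to 79.6% and 77.3% of WT, the p53 target median from 0.434 to 0.241 and the share of genes separated upwards from 15.5% to 7.54% and downwards from 0.35% to 3.24%. The limma tests were not affected, but separation and the order of genes named within classes were taken on scaled CPM, so the change of scale may have altered which of the passing genes are named. The class difference test was corrected after a first result of 0 genes, because it recovered none of the simulated changes while its variance trend was fitted on the difference and not on the level. A result past the threshold in no setting was counted as turned around only where a call was involved, a definition changed after many such changes of sign among the gene lists had been seen. The library sets were found from the data, and the term for them was added as an alternative. Also added were the log2 CPM scales with trimmed mean or median-of-ratios factors, voom and mean log of depth-scaled counts. So were leaving out proliferating cells and clusters built without called and cell cycle genes. Fixed in advance were no low-count filter, the replicate block, leaving out each library, stricter or no cell filters (750 genes and 5%), all kept cells, doublets kept, thinned depth, 50 cells per library and class and Leiden at 0.5 and 2. Count models named in advance as alternatives could not be run on these values.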

Results

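Single-cell transcriptomes were measured in heart cells sorted as endothelial from ApoE-deficient C57BL/6 mice, a strain prone to atherosclerosis, 8 weeks after transverse aortic constriction, a surgical narrowing of the aorta that loads the heart with pressure. The 3 WT libraries came from Cre-negative mice with intact Nogo-B. The 3 KO libraries came from Cre-positive mice labelled Nogo-B KO, in which the series describes a deletion of Nogo-A/B in endothelial cells. Nogo-B is a reticulon of the endoplasmic reticulum encoded by Rtn4 and is known to inhibit serine palmitoyltransferase, the first enzyme of sphingolipid synthesis. The title of the series sets S1P (sphingosine-1-phosphate) against ceramide, so genes of both branches were followed over all endothelial cells. Nothing in the labels says that each library came from a separate mouse, so p-values measure the spread between these libraries.

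The 6 libraries held 43405 cells, of which 40849 were kept and 26494 were endothelial. Endothelial cells numbered 3770, 4667 and 4040 in WT and 4441, 3649 and 5927 in KO. They made up 62.4% ± 8.0 (SD, n = 3) of kept WT cells and 67.9% ± 16.8 (SD, n = 3) of kept KO cells (exact two-sided permutation p = 0.8). Total counts per library were 30061436, 26683433 and 23505169 in WT and 33153227, 25384691 and 27229685 in KO, and the median count per cell lay between 3294 and 4154. The libraries also fell into 2 sets that crossed the groups. B cell-like cells made up 12.2% to 16.6% of kept cells in WT1, KO1 and KO2 but 0.29% to 0.51% in WT2, WT3 and KO3, and the first principal component of endothelial expression, 53.3% of the variance, separated the same sets. The library numbers in the labels run from 1 to 3 in the first set and from 4 to 6 in the other. These are called the B-cell-rich and B-cell-poor sets, and values within each set are given for the deleted gene and for some of the gene lists and genes named below.

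Endothelial clusters comprised capillary-like cells led by Car4, Cd36 and Kdr or by Cyp26b1, Aqp1 and Timp4, artery-like cells led by Sema3g, Gja5 and Fbln5, vein-like cells led by Igfbp5, Vwf and Prss23, and lymphatic-like cells led by Ccl21a, Mmrn1 and Lyve1. Endocardial-like cells were led by H19, Npr3 and Cytl1, interferon-high endothelial-like cells by Ifit1, Ifit3 and Ifit2, and angiogenic endothelial-like cells by Prnd, Apln and Kit. Proliferating endothelial-like cells were led by Cenpf, Mki67 and Top2a. Endothelial clusters 0 (Esm1, Slc1a1, Apold1, Ccn1), 3 (Samd5, Cysltr1, Lhx6, Fmo2) and 5 (Alpl, Hey1, Sema3g, Alox12) met no naming rule and are given by number. The remaining cells included B cell-like (Cd79a, Cd79b), T and NK cell-like (Trbc2, Cd3d or Gzma, Prf1), macrophage and monocyte-like (C1qa, C1qb), neutrophil-like (Retnlg, S100a9), dendritic cell-like (Naaa, Xcr1) and fibroblast-like (Gsn, Mfap5) clusters.

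The deleted gene was examined first. Rtn4 (chromosome 11, 29692947 to 29744331, plus strand, mm10) stood at 263, 241.7 and 240.3 CPM in WT endothelial cells and at 115.4, 129.2 and 127.5 CPM in KO endothelial cells, scaled by trimmed mean of M values. The KO mean was 49.9% of the WT mean (124 ± 7.5 against 248.3 ± 12.7 CPM, SD, n = 3), and every KO library lay below every WT library. The log2 ratio was -1.10 in the B-cell-rich and -0.92 in the B-cell-poor libraries. The limma test on mean log values per library gave an adjusted p of 0.160, above the threshold of 0.05, and the same test with a term for the library set gave 0.000887. The log2 ratio in the artery-like class was -1.22 (adjusted p = 0.0121), in cluster 0 -1.05 (adjusted p = 0.00413) and in cluster 3 -1.0 (adjusted p = 0.0124), and these 3 calls were the ones by limma on mean log values. In all 10 endothelial classes tested every KO library lay below every WT library (log2 ratio -0.80 to -1.55), and on scaled log2 CPM Rtn4 passed in 7 of them. The artery-like call was lost without KO1 or KO3 (highest adjusted p = 0.233) and the cluster 3 call without WT1 or KO1 (highest adjusted p = 0.135). An Rtn4 count was present in 49.5% ± 10.5 of WT and 35.7% ± 4.7 of KO endothelial cells (SD, n = 3; exact permutation p = 0.2, groups overlapping), and in 39.5% ± 6.3 and 25% ± 2.9 with every cell thinned to 2500 counts. The 3′ tag of this assay is shared by the Rtn4 isoforms and may lie outside the deleted part, so it checks the direction of the labels and not the extent of the deletion.

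Rtn4 was also lower outside the endothelium. Macrophage and monocyte-like cells held 293.9 ± 93.7 CPM in WT and 135.6 ± 14.2 CPM in KO (SD, n = 3), 46.1% of WT, with every KO library below every WT library. In T and NK cell-like cells the KO mean was 79.6% of WT (75.7 against 95.1 CPM) and in neutrophil-like cells 77.3% (122.5 against 158.4 CPM). In B cell-like cells it was 121.6% (98.5 against 81.0 CPM, groups overlapping), but WT2, WT3 and KO3 held only 30, 32 and 20 such cells. The log2 ratio there was -0.3 in the B-cell-rich libraries, with 982 to 1104 such cells each, and 0.84 in the B-cell-poor libraries. The exact permutation p was 0.1 in the macrophage, T and NK and neutrophil classes, which is the smallest that 3 against 3 libraries allow, and 0.4 in B cell-like cells. As mean count per cell, the scale first used, T and NK cell-like (89.3% of WT; exact p = 0.5) and neutrophil-like cells (90.2%; 0.7) overlapped between groups, so their separation holds on the CPM scale and not on that one. Among unnamed clusters the KO mean was 49.8% of WT in cluster 7 (led by Chil3, Lyz2 and Plac8), 49.6% in cluster 10 (Ear2, Apoc2) and 44.1% in cluster 17 (Cd209a, Siglech), with every KO library below every WT library in each (exact p = 0.1). Cluster 23 (Myl2, Tnni3; 60.6% of WT) carried pan-endothelial markers at the level of endothelial clusters, so its fall cannot be placed outside the endothelium.

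**Figure D1:**
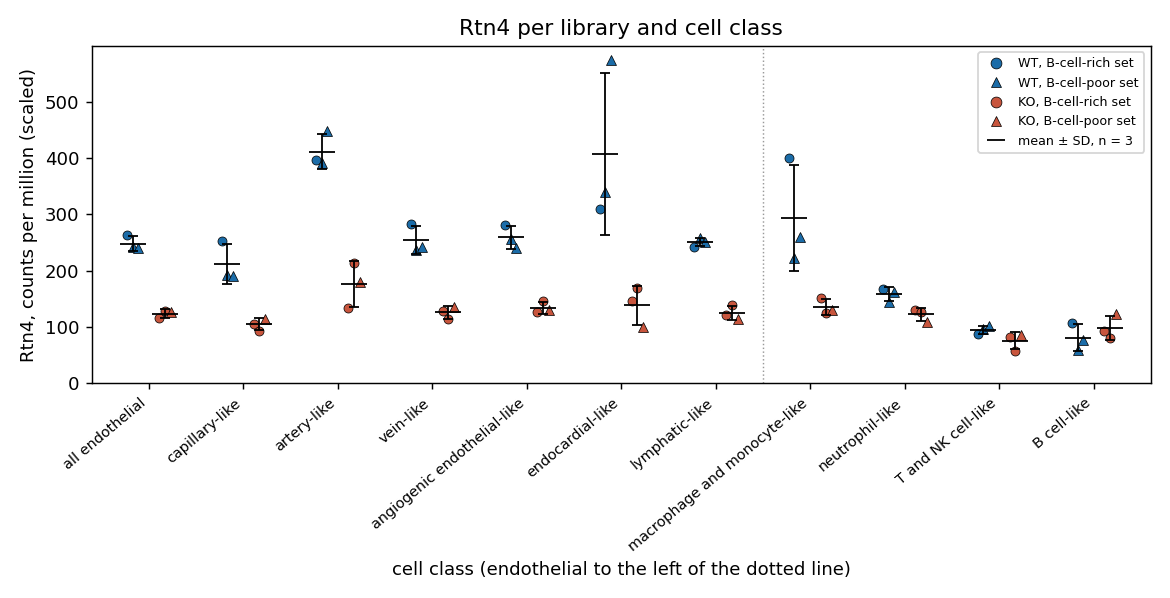
Rtn4 level per library in scaled CPM (vertical axis) by cell class (horizontal axis), WT in blue and KO in red, circles for B-cell-rich and triangles for B-cell-poor libraries, bars for the mean ± SD of 3 libraries. In all endothelial cells the KO libraries lay between 115.4 and 129.2 CPM and the WT libraries between 240.3 and 263 CPM, and the B cell-like class was the one drawn in which the groups overlapped.

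No gene of sphingolipid synthesis or signalling passed the test between KO and WT endothelial cells. No other gene passed it either, Rtn4 at 49.9% of its WT level included (limma adjusted p = 0.160). A missing call therefore does not show that these genes were unchanged. Sptlc1 and Sptlc2, which encode subunits of serine palmitoyltransferase, measured 38.2 ± 3.1 and 126.9 ± 2.9 CPM in WT and 41.2 ± 3.4 and 116 ± 8.0 CPM in KO (SD, n = 3; limma adjusted p = 0.569 and 0.736). The 3 KO values of Sptlc2 lay below the 3 WT values in CPM, while its tested difference in mean log2 value was above 0 (0.023). Ormdl3, a regulator of that enzyme, measured 48.7 and 48.5 CPM, the desaturase Degs1 104.5 and 107.8 CPM, and the ceramide synthase Cers2 99.5 and 96.4 CPM (adjusted p from 0.569 to 0.584). The sphingosine kinases Sphk1 (3.02 and 2.48 CPM) and Sphk2 (12.3 and 14.1 CPM) had adjusted p of 0.885 and 0.569, and the S1P exporter Spns2 (69.0 and 61.1 CPM) 0.965. For Ormdl3, Cers2 and Spns2 the tested difference was also above 0 (0.024, 0.041 and 0.003) although the KO mean in CPM was lower. The S1P receptor S1pr1 stood at 612.8 ± 139.3 CPM in WT and 693.8 ± 68.4 CPM in KO (log2 ratio 0.18, with -0.15 in the B-cell-rich and 0.46 in the B-cell-poor libraries). Its difference in mean log2 value was 0.27 (SE 0.17, adjusted p = 0.569). S1pr3 was too sparse to test, with 7 counts in WT and 12 in KO. Of the ceramide synthesis list 7 of 13 tested members were higher in KO (limma camera adjusted p = 0.401), of ceramide turnover 11 of 21 (0.983) and of S1P metabolism and receptors 6 of 12 (0.403). No member passed adjusted over all genes or adjusted over the list alone. The smallest p values belonged to the ceramide synthase Cers4 (111.5 and 116.2 CPM), the sphingomyelin phosphodiesterase-like Smpdl3b (2.38 and 3.92 CPM) and the receptor S1pr4 (7.24 and 9.68 CPM).

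Endothelial genes named in advance for flow and inflammation did not pass either. The flow-responsive factors Klf2 (1433 ± 379 and 1484 ± 199 CPM) and Klf4 (644.1 ± 205 and 535.5 ± 57.4 CPM) had limma adjusted p of 0.663 and 0.937, and Nos3, the endothelial nitric oxide synthase (182.4 and 181.3 CPM), 0.569. The leukocyte adhesion molecule Vcam1 measured 101.7 ± 22.3 CPM in WT and 120.3 ± 3.0 CPM in KO (SD, n = 3; adjusted p = 0.569), with a log2 ratio of -0.08 in the B-cell-rich and 0.44 in the B-cell-poor libraries. Icam1 (97.6 and 93.0 CPM), Sele (3.95 and 3.51 CPM) and Selp (14.2 and 18.3 CPM) had adjusted p of 0.606, 0.929 and 0.623. For Nos3, Icam1 and Sele the tested difference in mean log2 value was above 0 (0.077, 0.030 and 0.0006) although the KO mean in CPM was lower.

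Over all endothelial cells no gene of 13253 passed the limma test, while 1090 had an unadjusted p under 0.05, 1072 of them higher and 18 lower in KO. On log2 CPM of summed counts with trimmed mean scaling, or with voom, 3 genes passed: Csprs and Ltc4s rose and Rtn4 fell in KO, and the unadjusted split was 580 higher and 196 lower (499 and 260 with median-of-ratios scaling). With a term for the library set 193 genes passed, 162 higher and 31 lower in KO. Ltc4s, the synthase of leukotriene C4, stood at 33.9, 30.9 and 25.9 CPM in WT and 73.9, 76.1 and 68.1 CPM in KO (log2 ratio 1.15 in the B-cell-rich and 1.26 in the B-cell-poor libraries). The count of 0 became 114 without KO3, 10 without WT2 and 2 without KO2. The median log2 ratio of all genes was 0.197 as mean count per cell and 0.012 as scaled CPM, and CPM values are given for that reason.

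None of the genes with the smallest p passed by limma on mean log values. Those higher in KO were Gdf15, a stress-induced cytokine (1.91 ± 0.88 and 13.7 ± 5.5 CPM, SD, n = 3; limma adjusted p = 0.0825), and Csprs (18.1 ± 0.1 and 43.3 ± 5.9 CPM), the mitotic Ckap2 (3.89 and 13.2 CPM), the DNA helicase Hells (4.51 and 9.62 CPM), the phosphodiesterase Pde4b (67.8 and 101.2 CPM) and Malat1, each with an adjusted p of 0.0855. All of these but Malat1 had every KO library above every WT library, and Malat1 measured 25400 and 25380 CPM, so its difference existed in mean log values and not in CPM. Beside Rtn4, those lower in KO were the retinoic acid hydroxylase Cyp26b1 (109.9 ± 33.4 and 53 ± 2.3 CPM; adjusted p = 0.113), Asb4 (6.81 and 3.28 CPM; 0.274), Ddit4 (96.2 and 50.2 CPM; 0.427), the neutrophil-abundant S100a9 (62.3 and 29.2 CPM; 0.495) and Capn11 (4.39 and 0.427 CPM; 0.512). Cyp26b1 leads one capillary-like cluster, and the share of capillary-like cells is given with the other shares. With the library-set term, added after seeing the data, the limma adjusted p was 1.29e-05 for Gdf15 and Malat1. It was 0.000325 for Ckap2 and 0.00165 for Csprs, Hells and Pde4b. Cyp26b1 (0.0134), Asb4 (0.0241) and S100a9 (0.0468) also passed with that term, and Ddit4 (0.0609) and Capn11 (0.104) did not. Over all genes, 999 had every KO library above every WT library (7.54%) and 430 had the reverse (3.24%), where chance gives 5% each.

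**Figure D2:**
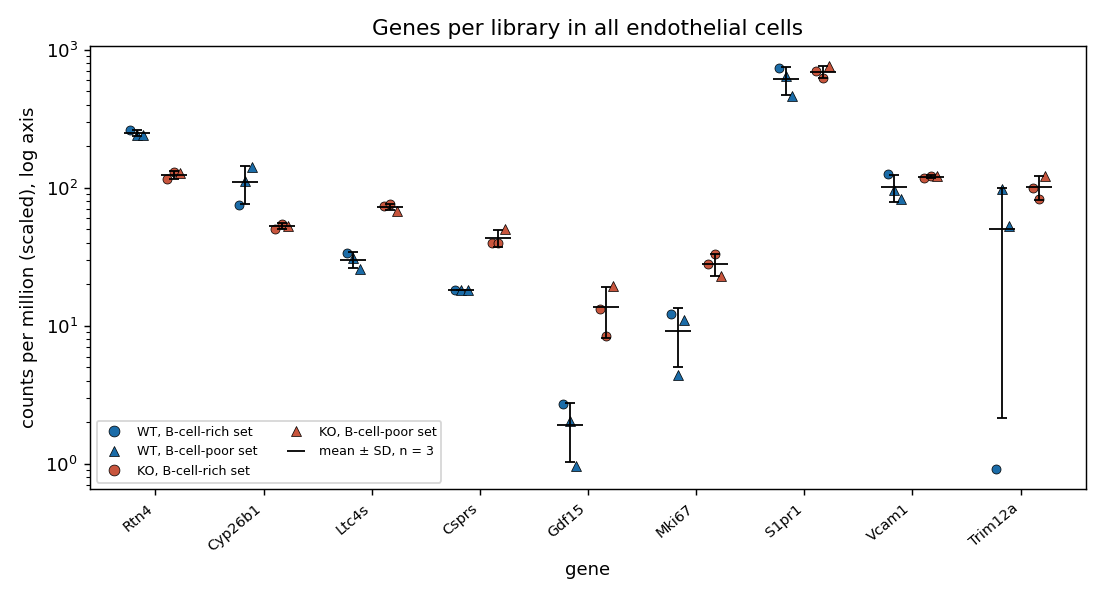
Level of 9 genes in endothelial cells per library in scaled CPM (vertical axis, log scale), WT in blue and KO in red, circles for B-cell-rich and triangles for B-cell-poor libraries, bars for the mean ± SD of 3 libraries. Gdf15 had KO values of 8.51 to 19.4 CPM above WT values of 0.968 to 2.70 CPM and Rtn4 the reverse order, S1pr1 and Vcam1 overlapped between groups, and Trim12a was 0.923 CPM in WT1 against 53.2 CPM or more in the other libraries.

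Of 27 gene lists fixed before the data were examined, 10 passed limma's camera with a preset correlation of 0.01, and none passed with an estimated correlation or with fry. When the 6 libraries were split into 3 and 3 in other ways, 7 to 13 lists passed, so the count of 10 does not by itself mark the genotype. Camera compares a list with all other genes, so rose and fell below give a direction relative to those genes. Of 1090 genes with an unadjusted limma p under 0.05, 1072 were higher in KO in mean log value. A list said to fall may therefore have risen less than other genes. With fry, which tests a list by itself, the laminar shear, hypoxia, TGF-beta, mitochondrially encoded and mesenchymal lists had the direction opposite to the one given below. Cell cycle genes rose in KO, with 32 of 32 members higher, a median log2 ratio of 1.26 (1.12 in the B-cell-rich and 1.02 in the B-cell-poor libraries) and an adjusted p of 6.6e-34, against an adjusted p of 0.75 with an estimated correlation. In 29 members every KO library lay above every WT library. No member passed over all genes, and 25 did adjusted over the list alone. With the library-set term, added after seeing the data, 19 of the 32 passed over all genes. The mitotic spindle gene Prc1 measured 5.44 ± 1.96 and 18.5 ± 3.7 CPM, the mitotic kinase Cdk1 6.64 ± 1.26 and 16.7 ± 1.9 CPM, the proliferation marker Mki67 9.20 ± 4.18 and 28.1 ± 5.1 CPM, and the ribonucleotide reductase subunit Rrm2 2.21 ± 0.85 and 7.92 ± 1.15 CPM (SD, n = 3). Without the proliferating endothelial-like cells the adjusted p became 0.0563.

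Interferon response genes rose in KO (camera adjusted p = 1.8e-10; adjusted p = 0.995 with an estimated correlation), with 33 of 34 members higher and 11 past the threshold adjusted over the list alone. The median log2 ratio was 0.327, but it was 0.714 in the B-cell-poor and -0.092 in the B-cell-rich libraries, so the difference did not hold within both sets. Bst2, a virus-tethering membrane protein, measured 486.8 ± 18.6 and 642.3 ± 85.0 CPM, Xaf1 131 and 158.5 CPM, the ubiquitin-like Isg15 93.9 ± 25.6 and 144.4 ± 10.0 CPM and Rtp4 76.7 and 104.2 CPM (SD, n = 3). Cytosolic ribosomal protein genes fell (adjusted p = 9.1e-25; adjusted p = 0.995 with an estimated correlation), all 71 lower in KO with a median log2 ratio of -0.253, which was -0.463 in the B-cell-poor and 0.013 in the B-cell-rich libraries. None of the 71 passed singly on either count, and Rps20 measured 2579 ± 487 and 1993 ± 185 CPM.

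Angiogenesis and tip cell genes rose (adjusted p = 0.0183; adjusted p = 0.995 with an estimated correlation), with 15 of 25 higher and a median log2 ratio of 0.039, 0.099 in the B-cell-rich and 0.158 in the B-cell-poor libraries. Adjusted over the list alone 2 passed, Apln, the apelin ligand of tip cells (28.4 ± 2.7 and 56.1 ± 14.6 CPM), and the Notch ligand Dll4 (221.8 ± 24.3 and 262.1 ± 10.7 CPM). The tip cell peptide Adm measured 27.3 and 44.2 CPM and the guidance receptor Robo4 179.8 and 203.7 CPM. Apln and Adm are among the leading genes of the angiogenic endothelial-like class, which made up 12.4% of WT and 19.7% of KO endothelial cells. Their rise over all endothelial cells is not separated here from that share. Cholesterol synthesis and uptake genes rose (adjusted p = 0.00907; 0.995 as the adjusted p with an estimated correlation), 22 of 27 being higher with a median log2 ratio of 0.088, 0.171 and 0.132 in the B-cell-rich and B-cell-poor sets. None passed adjusted over the list alone. The isoprenoid enzyme Idi1 measured 7.16 ± 1.24 and 10.0 ± 0.4 CPM, the demethylase Cyp51 3.46 and 4.58 CPM, and the exporter Abca1 106 and 112.4 CPM. The angiogenesis call was lost without WT1 (0.491), WT2 (0.0747) or KO3 (0.235), and the cholesterol call without WT1 (0.245) or KO3 (0.108).

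Genes of the laminar shear response fell (adjusted p = 0.00907; adjusted p = 0.995 with an estimated correlation), with 16 of 21 lower and a median log2 ratio of -0.142, -0.047 and -0.103 in the B-cell-rich and B-cell-poor sets. The one member past the threshold adjusted over the list alone went the other way, the phosphatase Dusp5 (4.98 ± 1.06 and 16.7 ± 6.0 CPM), and the heme oxygenase Hmox1 (16.2 and 19.4 CPM) was also higher. TGF-beta and BMP signalling fell (adjusted p = 0.00907; adjusted p = 0.995 with an estimated correlation), 21 of 29 being lower with a median log2 ratio of -0.117, -0.176 and -0.027 in the 2 sets. None passed singly on either count: the BMP target Id3 measured 1630 ± 330 and 1091 ± 185 CPM, Id2 81.7 and 57.4 CPM, and the ligand Bmp2, with the smallest p, 2.62 and 7.05 CPM. Hypoxia response genes fell (adjusted p = 0.00907; adjusted p = 0.995 with an estimated correlation), 12 of 19 being lower with a median of -0.077, -0.256 and -0.025 in the 2 sets and none past the threshold singly. Ddit4, an mTOR inhibitor, was lower and Adm higher, as given above, and Higd1a (78.5 and 80.3 CPM) and Ero1l (29.8 and 33.5 CPM) differed little. The shear call was lost without WT2 (0.148) or KO3 (0.171), the TGF-beta call without WT1 (0.0783), WT2 (0.0988) or KO1 (0.0547), and the hypoxia call without WT1 (0.0655) or WT2 (0.0747).

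Mitochondrially encoded transcripts fell (adjusted p = 0.00157; adjusted p = 0.995 with an estimated correlation), 10 of 13 being lower with a median log2 ratio of -0.136. The median was -0.349 in the B-cell-rich and 0.191 in the B-cell-poor libraries, the adjusted p with the library-set term was 0.359, and the call was lost without WT3 (0.288) or KO2 (0.432, direction turned). The mt-Nd2 transcript measured 1219 ± 244 and 1247 ± 465 CPM. Mesenchymal and matrix genes fell (adjusted p = 0.000956; adjusted p = 0.995 with an estimated correlation), although 14 of 25 were higher and the median log2 ratio was 0.032 against a mean of -0.184. The medians were -0.165 and -1.15 in the B-cell-rich and B-cell-poor sets, and without KO3 the adjusted p was 0.533 in the other direction. Collagen Col1a1 measured 25.1 ± 11.3 and 7.04 ± 9.49 CPM, Sparc 3030 and 3204 CPM, and Vim 1328 and 1492 CPM (SD, n = 3). Markers of fibroblasts, summed over endothelial cells, stood at 332.8 ± 193.1 CPM in WT and 215.1 ± 168.1 CPM in KO (exact permutation p = 0.5).

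**Figure D3:**
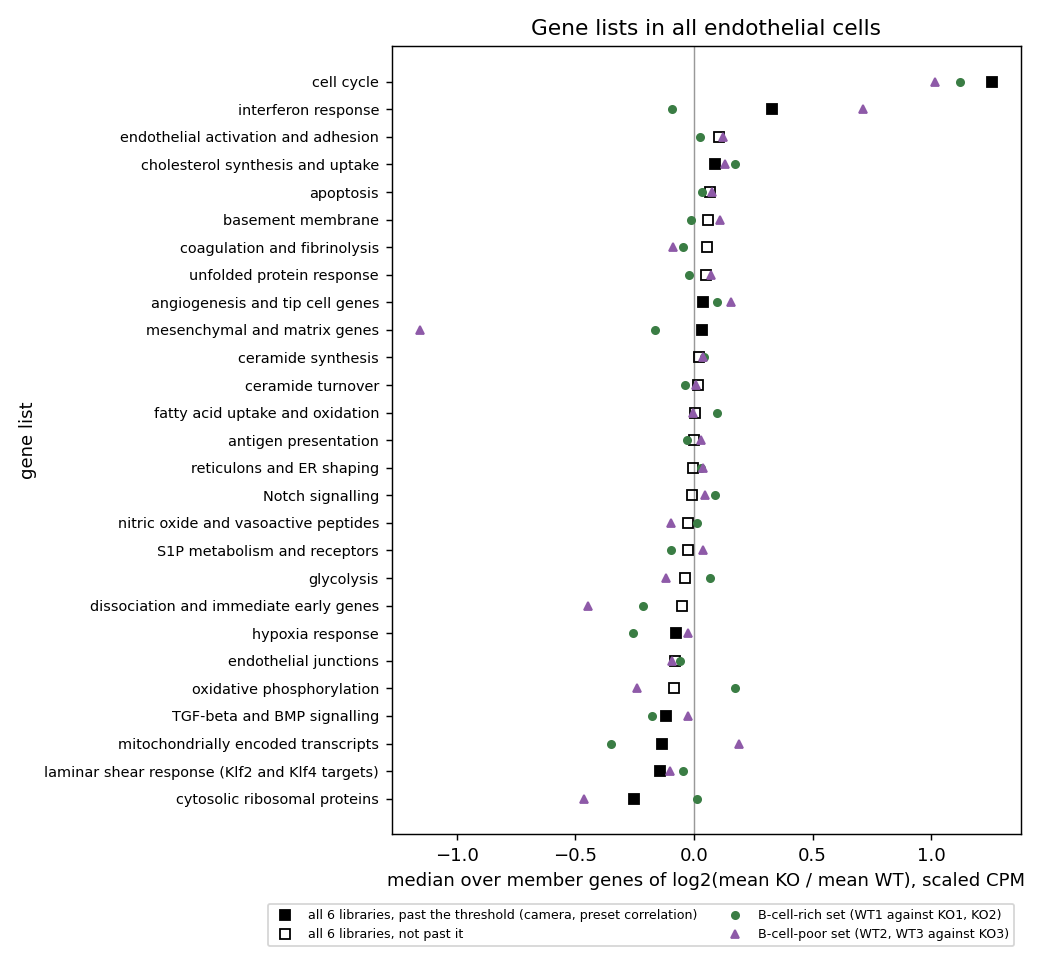
Median log2 ratio of KO over WT of the members of each gene list (horizontal axis; lists on the vertical axis), squares for all 6 libraries (filled where limma's camera passed at the preset correlation), green circles for the B-cell-rich and purple triangles for the B-cell-poor set. Cell cycle has medians of 1.26, 1.12 and 1.02, while interferon response and ribosomal proteins have medians of -0.092 and 0.013 in the B-cell-rich set.

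The remaining lists did not pass camera in the main test. Reticulons and ER shaping had 9 of 18 members higher (adjusted p = 0.983), and beside Rtn4, which passed adjusted over the list alone (0.0264), Rtn1 measured 57.7 and 67.7 CPM. Endothelial activation and adhesion had 18 of 27 higher (adjusted p = 0.526), with none past the threshold. The chemokines Cxcl9 (83.8 ± 9.3 and 106.7 ± 12.7 CPM), Cxcl10 (9.15 ± 8.25 and 21.0 ± 0.9 CPM) and Ccl2 (14 ± 6.9 and 28.7 ± 3.6 CPM) lay above WT in every KO library, and Cxcl1 (24.2 ± 12.1 and 40.1 ± 8.5 CPM) overlapped between groups. Antigen presentation (12 of 23 higher, 0.568), fatty acid uptake and oxidation (16 of 31, 0.403), glycolysis (9 of 22, 0.876) and oxidative phosphorylation (7 of 67, 0.341) had no member past the threshold on either count. The fatty acid transporter Cd36 measured 4851 ± 936 and 3525 ± 688 CPM, and it is a leading gene of a capillary-like cluster, a class whose share is given below. The unfolded protein response had 18 of 27 higher (0.0594), with Sesn2 (3.69 ± 1.64 and 9.15 ± 2.93 CPM) past the threshold over the list alone, and Notch signalling 8 of 19 (0.604), with its feedback gene Nrarp (121.5 ± 41.7 and 182.2 ± 3.9 CPM) and Dll4 past it. Apoptosis had 16 of 24 higher (0.356), with the pro-apoptotic Bax (143 ± 14.6 and 185 ± 7.8 CPM) past the threshold over the list alone. Among dissociation and immediate early genes (10 of 27 higher, 0.184), Nr4a1 (114.3 ± 84.9 and 368.5 ± 169.4 CPM) and Egr3 (5.63 ± 4.79 and 43.5 ± 31.2 CPM) passed over the list alone, and Egr1 measured 483.5 and 864.1 CPM. Nitric oxide and vasoactive peptides (8 of 20 higher, 0.932) had Apln past the threshold over the list alone. Endothelial junctions (9 of 21, 0.356; Cldn5 787.1 ± 279.4 and 1107 ± 214 CPM), basement membrane (12 of 16, 0.184) and coagulation and fibrinolysis (10 of 19, 0.604; Plau 3.67 and 7.74 CPM) had none. The camera direction was higher while the median log2 ratio was below 0 for oxidative phosphorylation (-0.086), Notch signalling (-0.010) and nitric oxide (-0.026), and it was lower with medians above 0 for coagulation (0.054) and fatty acid uptake (0.006). Glycolysis and S1P metabolism had means above 0 (0.007 and 0.004) beside a direction and median below it. Of the 6 sex-linked genes only Xist (1186 ± 237 and 965.4 ± 187.2 CPM) and Tsix were measured, and that list was not tested.

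Within single endothelial classes 72 gene-by-class results passed limma at an adjusted p under 0.05, 61 higher and 11 lower in KO. On scaled log2 CPM 24 were higher and 13 lower, and with the library-set term 180 were higher and 69 lower. The transcription factors Nr4a1 and Nr4a2 and the matricellular Ccn1 rose in more than 1 class. Nr4a1 and Egr3 belong to the dissociation and immediate early list, of which 10 of 27 members were higher in KO over all endothelial cells. Whether cell handling contributed to these rises was not tested. Nr4a1 rose from 104 ± 75 to 352.5 ± 134.5 CPM in angiogenic endothelial-like cells (SD, n = 3; adjusted p = 0.0356) and from 120.4 ± 45.7 to 399.2 ± 233.5 CPM in artery-like cells (0.0127). Nr4a2 rose from 8.34 to 27.9 CPM in the angiogenic class (0.0456), from 20.1 to 81.4 CPM in cluster 0 (0.0336) and from 14.6 to 49.4 CPM in cluster 3 (0.0378), where Egr3 rose from 2.44 to 23.9 CPM (0.0124). Ccn1 rose from 53.6 ± 20.1 to 164 ± 36.5 CPM in capillary-like cells (0.00587), from 36.8 to 93.9 CPM in cluster 3 (0.0423) and from 142.5 to 440.9 CPM in cluster 0 (0.0336), a cluster it helps to define. The phosphatase Dusp5 rose in the angiogenic class (7.10 to 28.7 CPM; 0.0451) and the kinase Sik1 in cluster 0 (40.5 to 105.2 CPM; 0.0175). Each of these lost the call without at least 1 library, which was WT3 for all but Ccn1 in capillary-like cells (0.0618 without WT1), and the highest adjusted p was 0.367 (Ccn1 in cluster 3). On scaled log2 CPM the calls ended for Nr4a1 (0.106 and 0.198), for Nr4a2 (0.106, 0.0864 and 0.109) and for Ccn1 in clusters 0 and 3 (0.104 and 0.130), in the order given above.

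Further genes passed in single classes, and a call in one class does not show a difference from the others. Ltc4s rose from 16.3 ± 1.0 to 49.8 ± 6.7 CPM in the angiogenic class (0.0346) and from 5.34 ± 0.17 to 33.2 ± 5.3 CPM in cluster 5 (0.0180), where the homeobox gene Hlx rose from 103 to 159.2 CPM (0.0180). Csprs rose in cluster 0 (15.7 to 38.4 CPM; 0.0336) and cluster 3 (18.8 ± 0.8 to 51.0 ± 5.1 CPM; 0.00384), and the interferon-inducible Ifi27l2a rose in vein-like cells (78.3 ± 25.4 to 249.7 ± 66.8 CPM; 0.000185). In cluster 0 Cebpd (308.8 to 118.2 CPM; 0.0253), Ddit4 (77.4 to 34.4 CPM; 0.0467) and Cyp26b1 (107 to 48.4 CPM; 0.0336) fell, in cluster 3 the IGF-binding Igfbp5 fell (335.2 to 146 CPM; 0.0124), and in endocardial-like cells Col1a1, a fibroblast marker, fell (1251 ± 109 to 169.9 ± 258.1 CPM; 0.0422). That call ended with the library-set term (0.307) and on scaled log2 CPM (0.572). Lymphatic-like cells, with 20 cells in the smallest library, had 17 genes higher and 3 lower, 2 and 0 on scaled log2 CPM and 32 and 9 with the library-set term. The cell cycle inhibitor Cdkn1a rose there from 79.5 ± 29.3 to 386 ± 40.2 CPM (4.1e-05) and its fellow p53 target Phlda3 from 31.2 ± 20.4 to 203.9 ± 83.3 CPM (0.000502). Gap43 (17.7 to 132.9 CPM; 0.00521) and Lhfp (34.6 to 100.7 CPM; 0.0454) also rose, and Apoe (131.8 to 23.7 CPM; 0.0268) and Fgl2 (2447 to 1238 CPM; 0.0177) fell. The labels give all mice as ApoE-deficient without naming the allele, so what the remaining Apoe transcript stands for is not known here, and its call was lost without KO2 or KO3 (highest 0.222). Interferon-high endothelial-like cells had no call by limma on mean log values or on scaled log2 CPM (631 at an unadjusted p under 0.05), and 7 genes higher and 3 lower with the library-set term. Of the 31 genes named in a class, 16 passed on scaled log2 CPM and 30 with the library-set term. Of the same 31, 26 lost the call without at least 1 library (17 without WT3, 15 without KO1), and the 4 that kept it without each of the 6 were Rtn4 in cluster 0, Csprs in cluster 3, Cdkn1a in lymphatic-like and Ifi27l2a in vein-like cells.

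Whether the KO effect differed between classes was tested on the difference between the class values of each library. Against vein-like cells, capillary-like cells differed in 3 of 9940 genes. Ifi27l2a had a KO difference of 0.061 in mean log2 value in capillary-like and 0.362 in vein-like cells (limma adjusted p = 8.7e-05), which held without each library (highest 0.00679). In CPM it went from 19.2 to 43.7 in capillary-like and from 78.3 to 249.7 in vein-like cells, higher in KO in both, so the gap in mean log2 value cannot be separated from the lower level in capillary-like cells. The immediate early gene Egr1 differed by 0.641 and 0.194 (0.0182) and the growth factor Igf1 by 0.001 and -0.259 (0.0182), and both lost the call without single libraries (highest 0.121 and 0.147). Igf1 is a defining gene of the vein-like cluster (348 and 224 CPM there, 4.30 and 3.84 CPM in capillary-like cells). Against artery-like cells, 1 of 9037 genes differed, the actin-binding Tmsb4x (-0.020 and 0.154; adjusted p = 0.00732), which was lost without WT3, KO1 or KO2 (highest 0.451). Tmsb4x measured 13260 and 12630 CPM in capillary-like and 6850 ± 1022 and 6806 ± 503 CPM in artery-like cells, so the higher mean log value in KO artery-like cells was absent in CPM. On scaled log2 CPM the adjusted p was 0.954 for Tmsb4x, 0.975 for Ifi27l2a and Igf1 and 0.0004 for Egr1. Next by p and not past the threshold in this test were Pgf, Alox12 and Slc45a4 against artery-like cells and Vcam1 against vein-like cells. Vcam1 passed with the library-set term (0.00394) and without KO2 (0.00497) but not on scaled log2 CPM (0.998), Alox12 passed without KO2 (0.0385) and Slc45a4 without KO3 (0.00632).

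Among all the class and cluster shares compared, those of 4 classes separated the groups completely. Chance alone gives complete separation in 10% of shares, so some are to be awaited among so many. Angiogenic endothelial-like cells made up 10.7%, 12.2% and 14.2% of WT and 17.3%, 22.4% and 19.6% of KO endothelial cells (12.4% ± 1.8 and 19.7% ± 2.6, SD, n = 3; exact permutation p = 0.1). Proliferating endothelial-like cells made up 0.504%, 0.279% and 0.520% in WT and 1.53%, 1.81% and 1.23% in KO (0.434% ± 0.135 and 1.52% ± 0.29; exact p = 0.1). Neutrophil-like cells made up 4.37%, 6.59% and 8.17% of kept WT cells and 1.72%, 1.79% and 1.54% of kept KO cells (6.38% ± 1.91 and 1.68% ± 0.13; exact p = 0.1), and cluster 7, led by Chil3, Lyz2 and Plac8, 2.76% ± 0.89 and 1.38% ± 0.35 (exact p = 0.1). Clusters were also built without 287 genes, those called in any test together with the cell cycle list. The shares were then 15.4% ± 1.0 and 23.2% ± 3.2 for the angiogenic class and 6.73% ± 1.85 and 1.74% ± 0.19 for neutrophil-like cells, exact p = 0.1 each. With no cell filter and clusters built anew, the angiogenic shares were 5.71%, 7.46% and 10.6% in WT and 8.46%, 13.7% and 10.8% in KO, which overlapped (exact p = 0.2). A p of 0.1 is the smallest this design can give, so none of these could pass 0.05. Capillary-like cells made up 16.4%, 29.4% and 43.7% of WT and 15.5%, 8.36% and 23% of KO endothelial cells (exact p = 0.2), lower in KO within each set of libraries. Artery-like cells (2.34% and 3.45%; exact p = 0.2), vein-like cells (4.36% and 5.21%; 0.7), interferon-high cells (4.95% and 7.0%; 0.4), endocardial-like cells (1.63% and 2.25%; 0.7) and lymphatic-like cells (1.00% and 0.946%; 0.9) overlapped between groups. The artery-like share depended on the clustering: it was 23.6% and 23.3% with doublets kept and 11.8% and 10.9% at Leiden 0.5, where every KO library lay below every WT library (exact p = 0.1), and the vein-like share was 12.3% and 12.9% with no cell filter. The same overlap was seen for clusters 0, 3 and 5 and for B cell-like (exact p = 0.7), T and NK cell-like (0.5), macrophage and monocyte-like (0.7) and fibroblast-like cells (0.4). The cells had passed a sort for endothelial cells, so shares of other cells are what that sort let through.

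**Figure D4:**
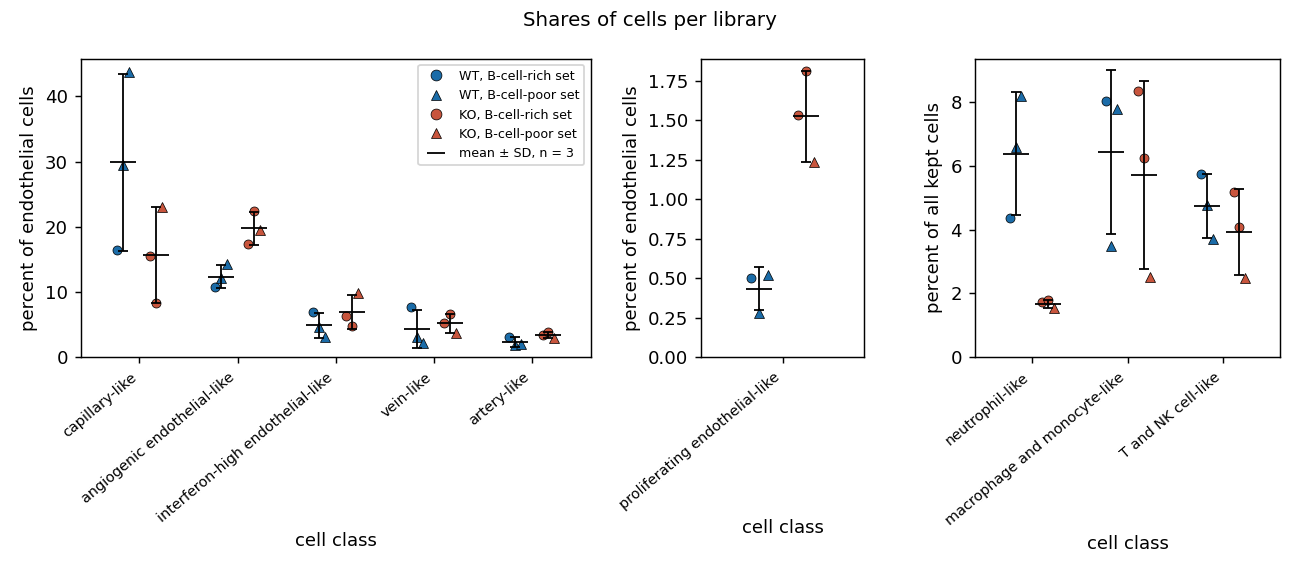
Share of endothelial cells (left and middle panels) and of all kept cells (right panel) in percent (vertical axes) per library by class, WT in blue and KO in red, circles for B-cell-rich and triangles for B-cell-poor libraries, bars for the mean ± SD of 3 libraries. Angiogenic (17.3% to 22.4% against 10.7% to 14.2%) and proliferating endothelial-like cells lay higher in each KO library and neutrophil-like cells lower, while capillary-like shares overlapped.

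Marker genes of other cell types had low summed levels in endothelial cells, and these sums do not show which cells the transcripts came from. The B cell sum lay between 318.1 CPM in KO3 and 404.5 CPM in KO1, while B cell-like cells made up 0.29% to 16.6% of kept cells. It was 330.2 CPM in WT1 and 341.6 CPM in WT2, so it followed that share little. Summed neutrophil markers stood at 123.5 ± 51.2 CPM in WT and 60.4 ± 18.0 CPM in KO (SD, n = 3; exact permutation p = 0.2), Schwann cell markers at 19.6 ± 1.8 and 24.7 ± 0.6 CPM (exact p = 0.1) and macrophage and monocyte markers at 51.9 ± 26.4 and 83.2 ± 66.3 CPM (exact p = 0.6). Erythrocyte markers reached 833.6 CPM in KO3 and 2.9 to 65.1 CPM in the other libraries. Markers of pericytes (45.4 and 49.4 CPM), smooth muscle (76.8 and 80.0 CPM), cardiomyocytes (79.4 and 77.1 CPM), dendritic cells (105.5 and 133.1 CPM), T and NK cells (5.9 and 8.9 CPM), B cells (336.4 and 353.5 CPM), platelets (27.6 and 27.5 CPM) and mesothelium (67.9 and 77.9 CPM) had exact p from 0.3 to 1.0. Pan-endothelial markers stood at 12843 ± 1202 and 13195 ± 691 CPM (exact p = 0.7).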

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

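The test of the class difference was planned, and the test of the proliferation markers outside the endothelium was chosen after the result was seen. Tmsb4x, Ifi27l2a, Egr1 and Igf1 are listed because their KO effect differed between endothelial classes by limma's test of the difference itself. The KO effect in capillary-like less that in artery-like cells was -0.174 for Tmsb4x, and the effect in capillary-like less that in vein-like cells was -0.302 for Ifi27l2a, 0.447 for Egr1 and 0.259 for Igf1, in mean log2 value. Tmsb4x stood at 6850 and 6806 CPM in WT and KO artery-like cells. Ifi27l2a stood at 19.2 and 43.7 CPM in capillary-like and 78.3 and 249.7 CPM in vein-like cells, and Igf1 at 4.30 and 3.84 CPM and at 348 and 224 CPM. On scaled log2 CPM the difference between classes had an adjusted p of 0.954 for Tmsb4x, 0.975 for Ifi27l2a and Igf1 and 0.0004 for Egr1. Of the 10 splits of the 6 libraries, 3 gave as many genes whose effect differed, the real one included, with 4 genes in the real split and 9 in the highest other. These splits are too few for a share under 0.05.

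Macrophage and monocyte-like cells were not part of the planned expression comparisons. At least 2 of 7 proliferation markers were detected in 1.31% ± 0.09 of WT and 3.96% ± 1.97 of KO macrophages and monocytes (SD, n = 3; exact permutation p = 0.1, the smallest possible), with every KO library above every WT library (4.19%, 1.89% and 5.81%). Clusters 20 and 36 of this class hold most of their cells from KO1 (83 of 113 and 30 of 31). Without them the shares were 1.33% ± 0.11 and 3.99% ± 2.01 (exact p = 0.1). The same measure was 0.475% and 1.80% in endothelial cells (exact p = 0.1) and 0.803% and 2.05% in T and NK cell-like cells (exact p = 0.3, groups overlapping). In B cell-like cells it was 0.030% and 0.034%, and the median count per cell was 4499 in macrophages and 3804 in B cell-like cells.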

How the results depend on the processing

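The settings named as added in the processing account, the library-set term, the CPM scales and voom among them, were chosen after seeing the data, and the cause of the changes below was not tested unless stated. The count models planned as alternatives were not run, because the values are not raw counts. The replicate numbers gave no clear pairing of the libraries. Same-numbered WT and KO libraries had correlations of deviations of -0.026, 0.106 and 0.464, the last being the highest of all pairs. KO1 and KO2 correlated better with WT2 (0.316) and WT1 (0.283). So few values, taken from means of 3 libraries, cannot exclude a pairing. With the replicate numbers as a block, limma gave 238 genes over all endothelial cells, 239 within classes and an Rtn4 adjusted p of 0.000284. Over all endothelial cells the count of 0 became 193 with the library-set term and 3 with trimmed mean, median-of-ratios or voom scaling, and 0 to 114 without single libraries. The Rtn4 adjusted p of 0.160 became 0.000887, 0.0134, 0.0140 and 0.0233 in those settings. Within classes the count of 72 became 19 with no low-count filter, 249 with the library-set term, 37 with trimmed mean, 40 with median-of-ratios and 35 with voom scaling, and 42 to 170 without single libraries. The 4 class differences became 0 with no low-count filter, 8 with the library-set term, 8 with median-of-ratios scaling and 1 to 15 without single libraries. Of the 10 lists called, 0 passed with an estimated correlation, alone or with the library-set term or log2 CPM, 0 with fry and 6 with median-of-ratios scaling.

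Some lists changed direction. Fry tests a list by itself and camera tests it against all other genes, so their directions answer different questions. With fry the adjusted p was 0.725 for laminar shear and hypoxia, 0.895 for mitochondrially encoded transcripts, 0.640 for TGF-beta and 0.790 for mesenchymal genes, each in the other direction. Over all kept cells activation and adhesion had 0.0255 and mitochondrially encoded transcripts 0.502. Oxidative phosphorylation passed as lower with trimmed mean (0.000662) and median-of-ratios scaling (0.000442). Of the other lists not called, dissociation genes passed in 6 alternatives and the unfolded protein response, basement membrane and coagulation in 3 each. Antigen presentation passed in 2 and glycolysis in 1. Without single libraries the adjusted p ranged from 1.122e-09 to 0.432 for mitochondrially encoded, from 5.71e-13 to 0.533 for mesenchymal and from 8.509e-06 to 0.401 for dissociation genes. Of the lists, 0 passed in every alternative and 9 of 27 in no setting, and 16 of the 17 not called had another sign in at least 1 alternative. Of 27 genes named over all endothelial cells beside Rtn4, 16 passed in no setting and 12 changed sign in at least 1. Of 31 named within classes, 1 passed in every alternative, Cdkn1a in lymphatic-like cells. Among shares, the KO less WT difference moved to 3.05 points for the angiogenic class with no cell filter, where the groups overlapped. It moved to -7.18 with doublets kept and -7.28 at Leiden 0.5 for neutrophil-like cells. For proliferating endothelial-like cells it moved to 0.847 with clusters built without called and cell cycle genes. The artery-like difference of 1.12 points turned to -0.317 with doublets kept and -0.94 at Leiden 0.5. In simulated libraries of 1000 cells, fewer than the real ones hold, and without the library sets, 20% of 1.5-fold rises over all endothelial cells were recovered.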

Other observations

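The tests of p53 targets, the one between library sets among them, of interferon genes outside the endothelium, of Rtn4 in macrophages and of the Trim cluster were chosen after the result was seen. Among targets of p53, the DNA damage response factor, 37 of 44 listed genes were higher in KO endothelial cells, with a median log2 ratio of 0.241 against 0.012 for all genes. Gdf15 stood at 1.91 ± 0.876 CPM in WT and 13.7 ± 5.46 CPM in KO (SD, n = 3), Phlda3 at 41.0 ± 8.99 and 74.5 ± 9.19 CPM, Zmat3 at 9.29 ± 0.972 and 17.1 ± 1.09 CPM, Eda2r at 9.90 and 17.8 CPM, Sesn2 at 3.69 and 9.15 CPM and Bax at 143 and 185 CPM. In 11 members every KO library lay above every WT library, a separation that chance gives in 5% of genes in that direction and that 7.54% of all genes tested showed. Fas went the other way (122 and 91.2 CPM), and Cdkn1a (361 and 397 CPM) and Mdm2 (48.2 and 59.4 CPM) overlapped between groups over all endothelial cells.

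Interferon response genes had a median log2 ratio of 0.327 in endothelial cells, with -0.092 in the B-cell-rich and 0.714 in the B-cell-poor libraries. Outside the endothelium the median was 0.471 in neutrophil-like cells (-0.346 in the B-cell-rich and 1.19 in the B-cell-poor libraries), 0.369 in macrophage and monocyte-like cells (0.008 and 0.808), 0.503 in B cell-like cells (0.085 and 0.638) and 0.153 in T and NK cell-like cells (0.055 and 0.178).

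The p53 pattern passed limma's camera at a preset correlation (p = 5.4e-07) but not with an estimated one (p = 0.248) or fry (p = 0.0529). The median of the targets averaged over T and NK cell-like, B cell-like and neutrophil-like cells was -0.103. Of the 44 genes tested in endothelial cells, 33, 32 and 24 were tested there. This argues against a difference of the same size in every cell type. As the list was chosen after endothelial values had been seen, a lower value in other cells is in part to be awaited. The endothelial median was 0.238 without the proliferating class, which argues against more cycling cells of that class as the cause. The values also argue against the library set as the whole cause. KO holds 2 B-cell-rich libraries and WT 1, so the targets would have to differ between the sets by 0.723, and they differed by a median of 0.109 (upper quartile 0.229). The lower of the medians within sets was 0.219, but each set has an arm of 1 library, so that value alone excludes nothing. Only 10 splits of the libraries exist, and 1 of them, the real one, gave a camera p as small (6.26 as −log10 p, with 4.92 as the highest other), too few for a share under 0.05. Cre recombinase itself may raise p53 targets and cannot be told apart from the loss of Nogo, because 0 Cre-positive libraries with an intact gene exist here. A p53 response of the endothelium to the genotype therefore stays a hypothesis.

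Rtn4 stood at 49.8%, 49.6% and 44.1% of WT in the non-endothelial clusters 7, 10 and 17, whose pan-endothelial scores were -4.29, -4.05 and -4.36. In macrophages and monocytes it stood at 46.1%. Endothelial RNA or doublets among the macrophages cannot account for that value, since pan-endothelial markers reached a median of 0.85% of their endothelial level in WT macrophages, where 63.8% would be needed. A difference acting on every cell type stays open and cannot be told apart: the log2 ratio averaged over T and NK cell-like, B cell-like and neutrophil-like cells was -0.14, but those classes ranged from -0.37 to 0.28. The highest, in B cell-like cells, was -0.3 in the B-cell-rich and 0.84 in the B-cell-poor libraries, which hold 20 to 32 such cells each. Recombination of the gene in myeloid cells may be another explanation, as some endothelial Cre lines are active in blood cells, and it was not tested because the Cre line is not named.

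Trim12a, Trim5, Trim30d and Trim34a of the Trim cluster on chromosome 7 stood at 0.0659 to 8.04 CPM in WT1 endothelial cells and at 11.1 CPM or more in the other libraries. Trim30a (101 CPM in WT1, 103 to 123 CPM elsewhere) and Trim12c (82.7 CPM in WT1, 47.7 to 61.9 CPM elsewhere) showed no such gap. In endothelial cells Trim12a (104299894 to 104315466, mm10) stood at 0.923, 97.7 and 53.2 CPM in WT and 99.8, 83.1 and 122.5 CPM in KO, and the cluster had a median log2 ratio of 0.507, with 1.29 in the B-cell-rich and 0.406 in the B-cell-poor libraries. A stretch of chromosome 7 that differs between the mice may explain this: the median ratio averaged 0.797 over T and NK cell-like, B cell-like and macrophage-like cells, and the median was above 0 in each of these and in neutrophil-like cells (1.15), though KO and WT libraries overlapped in most members. The interferon response as a whole had a median of 0.327, which leaves it open as a part of the difference. Its endothelial median was 0.714 in the B-cell-poor libraries. In the B-cell-rich libraries, where WT1 is the only WT library, it was -0.092. The low values of the cluster in WT1 thus had no counterpart in the interferon list. The first 4 genes were lowest in WT1 and next lowest in WT3, which would suit a segregating allele, a hypothesis that genotypes of the mice could test.

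Splits of the 6 libraries were counted for each test, and 10 splits are too few for a share under 0.05. Over all endothelial cells the real split gave 0 genes and the highest other 1287. With a count of 0 all 10 of 10 give as many, so this count decides nothing. On log2 CPM the real split gave 3 genes and the highest other 134, and at an unadjusted p under 0.05 the values were 1090 and 4433, with 2345 in a further split. Within classes the real split gave 72 and the highest other 479, with 2 of 10 as large. For gene lists the values were 10 and 13, with 3 of 10, and every other split called at least 7 lists. The highest other split was the B-cell-rich against the B-cell-poor libraries for the first 2 tests, and a count that large points to a structure of the samples. With a term for that set the counts were 193 over all endothelial cells and 249 within classes.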
